A study of Mus musculus with 6 samples.

How the data were processed

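RNA was sequenced from whole lung of 6 mice, 3 WT and 3 KO for *Clec7a*, taken at day 14 after bleomycin. Per the labels' protocols, RNA was extracted with TRIzol and the libraries were made with an NEBNext Ultra kit. Whether that kit's product marked strand and which strand setting was used for counting are not given in the sources used here. The read counts per gene were deposited by the authors as whole numbers, 1 column per sample, with no normalization. The FPKM values (fragments scaled to gene length and to mapped fragments) were deposited by the authors in a second table for the same genes. HISAT2 2.0.4, StringTie 1.3.4d and the genome build GRCm38 are named in the submitters' processing notes, without their roles. Aligner and counting settings, the annotation release and the treatment of reads shared between similar genes are not given in the sources used here. Near-identical family members, overlapping genes and antisense pairs are therefore uncertain.

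The count table had 26100 rows, of which 22036 carried an Ensembl identifier and 4064 were models named as new genes without coordinates. Symbols were taken from the table, and coordinates and gene types from GENCODE M21, which uses GRCm38. It held 15241 of the 15243 Ensembl identifiers that were tested. Count columns were matched to samples by group and replicate number. The KO columns of the FPKM table carry a suffix that no label explains, so they were assigned to the KO group without replicate numbers. Design information states separate mice for each library, and p-values measure the spread between these 6 samples. Totals were between 31052936 and 34451956 counts, and at this depth counting error matters mainly for genes of low level.

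The main test was edgeR (4.0.16, R 4.3.3): genes were kept by its filterByExpr function, which left 16633 rows including 1390 of the new models, libraries were scaled by TMM factors, and a robust quasi-likelihood fit with genotype as the only term was tested 2-sided. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and 0.05 was the threshold. CPM values are counts scaled to library size with the TMM factors. Standard errors (SE) of edgeR fold changes were derived as the absolute log2 fold change over the square root of the test's F statistic. They are therefore not a measure of precision separate from the unadjusted p. Alternatives to this fit were DESeq2 (1.42.0) with its own size factors and filtering, limma-voom (limma 3.58.1) with and without sample weights, edgeR with DESeq2 size factors or with total counts only, a non-robust prior, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, and the replicate number as a block. The FPKM table was tested with limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes of at least 0.5 FPKM in at least 3 libraries, and without that filter. Fold changes on that scale understate the change of low genes. Each library was also left out in turn. These choices, the gene lists and the rule for named genes were fixed before the data were examined. A further 3 alternatives were chosen after seeing the data: both replicate 1 libraries left out, 1 surrogate variable from sva (3.50.0) added to the design, and the newer quasi-likelihood fit of edgeR.

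The fixed lists numbered 45, with 1161 entries of which 1140 were found in the table. They cover cell types of the lung and its immune cells, matrix and fibrosis, signalling, stress, tissue that could be carried along at dissection, and genes beside *Clec7a*. The 44 lists with at least 5 tested members were tested with limma's camera on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, adjusted over the lists. The sex-linked list had 4 tested members and was not tested. Camera compares a list with all other genes. It was repeated with a correlation estimated for each list, and fry, which asks whether a list's genes move on balance in 1 direction, was run beside it. A list's median and mean fold change describe its members only.

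The rule for named genes took *Clec7a*, then up to 12 genes in each direction that passed the threshold, had no overlap between groups, a mean of at least 1 CPM and a symbol that was not a predicted model, a pseudogene or an antigen receptor segment. Where fewer than 5 passed, the rule filled to 5 by smallest unadjusted p, which applied in both directions here. For each list described it named up to 4 passing members, filled to 2 with those of highest mean CPM. Because no gene passed, the ranking was extended to 12 per direction and up to 2 members of smallest p were added per list, after the values were seen. A member of the interferon response list that the rule named is not reported here.

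The scripts were tested on simulated counts for the 16633 genes with the real means, spread and library sizes and 200 changed genes. edgeR recovered 6%, 74%, 88% and 98% of genes changed 2-, 4-, 8- and 16-fold and called 13 unchanged genes. DESeq2 recovered 36%, 88%, 98% and 100% and called 76 unchanged genes. A list raised 2-fold had an adjusted p of 8.6e-16 with the preset correlation, 0.0305 with the estimated one and 0.0016 with fry. Fry also called 2 lists that shared no gene with it, and both camera versions called 0. The simulated genes were drawn independently, so the correlation between genes that affects list tests was absent. The simulation therefore does not show how often the list tests err on the real libraries. In other groupings of the 6 real libraries camera at the preset correlation called 10 to 25 lists and fry called 0.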

Results

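Lung tissue was taken from 6 mice at day 14 after bleomycin had been instilled into the airways, 3 of them wild type (WT) and 3 lacking *Clec7a* (KO). Bleomycin is a DNA-damaging drug that injures the alveolar epithelium and is followed by scarring, and *Clec7a* encodes dectin-1, a myeloid C-type lectin receptor for beta-glucan. RNA sequencing of whole lung reads a mixture of cell types, so each value below is a level per tissue and not per cell. The libraries held 31052936 to 34451956 counts each, and between 18953 and 19942 gene rows had at least 1 count. The Y-linked gene *Ddx3y* was read in all 6 libraries, at 112 to 137 CPM (counts scaled to library size). Saline-treated lungs were not analysed here, so the comparison is between genotypes within injured lungs. The question it addresses is how the lung transcriptome differs without *Clec7a* in this fibrosis model.

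The first replicate of each genotype stood apart from the other libraries. Spearman correlations across the tested genes were 0.959 or higher for pairs without a first replicate and 0.947 or lower for pairs with one. In KO replicate 1, mitochondrially encoded transcripts took 7.34% of the counts, against 2.69% to 3.87% in the other 5 libraries. WT replicate 1 had the highest mean level of secretory airway genes, 2.13 log2 units above the mean of the 6 libraries, and WT replicates 2 and 3 lay 1.23 and 1.97 units below it (-1.23 and -1.97). The mean of the fibrillar collagen list was -0.66 and -1.63 in WT and KO replicate 1 on the same centred scale.

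*Clec7a* itself (ENSMUSG00000079293, GRCm38 chromosome 6, 129461591 to 129472779, minus strand, annotated as a polymorphic pseudogene) was lower in every KO library than in any WT library. The WT libraries held 1974, 2732 and 6734 counts, and the KO libraries held 114, 230 and 92. Mean levels were 113.7 ± 72.7 CPM in WT and 4.43 ± 2.13 CPM in KO (SD, n = 3 each), a 25.6-fold difference with a log2 fold change (KO minus WT, as throughout) of -4.68 ± 0.61 (SE). The unadjusted p of edgeR was 1.65e-04 and its Benjamini-Hochberg adjusted p was 0.203. DESeq2 gave an adjusted p of 1.52e-14. Reads remaining in KO lungs were not assigned to exons, since the files give counts per gene.

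Among single genes, those of smallest p that were lower in KO included a growth-associated chromatin gene, macrophage genes and a cold-inducible gene. *Hmga2*, a chromatin architectural gene active in embryonic tissue, was at 8.62 ± 1.19 CPM in WT and 0.18 ± 0.11 CPM in KO, 46.1-fold lower (log2 fold change -5.53 ± 0.53). *F13a1*, the coagulation factor XIII A chain made by macrophages, was at 399.0 ± 99.97 CPM in WT and 66.7 ± 14.8 CPM in KO (log2 fold change -2.58 ± 0.29). The cold-inducible RNA-binding gene *Cirbp* (-1.73), the glycosyltransferase gene *Galnt15* (-1.91) and the inflammasome receptor gene *Naip6* (-5.89, from 13.6 ± 7.4 to 0.23 ± 0.16 CPM) completed the 5 that the fixed rule named. *Naip6* belongs to a family of near-identical genes, and how the submitters' counting divided shared reads is not given, so its value is uncertain. The next 7 by the same ranking, a number chosen after the values were seen, were *Gjb5* (-2.44), *Ms4a4a* (-2.44), *Lrp8* (-1.38), *Wnt9b* (-3.09), *Hgsnat* (-0.98), *Tnfrsf23* (-1.28) and *Vsig4* (-4.48). *Vsig4*, a complement receptor of tissue macrophages, was at 19.7 ± 7.8 CPM in WT and 0.88 ± 0.61 CPM in KO. On GRCm38, *Hmga2* lies on chromosome 10 from 120361275 to 120476469, *F13a1* on chromosome 13 from 36867178 to 37050244 and *Naip6* on chromosome 13 from 100281121 to 100317674, all 3 on the minus strand and annotated as protein coding.

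In the other direction, *Xcr1*, the chemokine receptor of cross-presenting dendritic cells, was at 0.74 ± 0.09 CPM in WT and 5.72 ± 1.16 CPM in KO (7.65-fold, log2 fold change 2.94 ± 0.34). The alcohol dehydrogenase gene *Adh1* stood at 51.0 ± 3.2 and 126.7 ± 13.2 CPM (log2 fold change 1.31 ± 0.16). *Thap2* (1.68), the HSP90 co-chaperone gene *Chordc1* (1.08) and *Dpp4* (1.53), a peptidase gene that marks adventitial fibroblasts, were the other 3 named by the fixed rule. The next 7, again a number chosen afterwards, were *Negr1* (2.30), *Pcolce2* (1.28), *Hc* (2.97), *Hsph1* (1.68), *Tcf21* (2.46-fold), *Klrc2* (2.78) and *Hepacam2* (2.14). *Hc*, which encodes complement C5, had 29.1 ± 1.5 CPM in WT and 228.0 ± 113.5 CPM in KO, and *Tcf21*, a transcription factor of lung fibroblasts, had 15.4 ± 2.4 and 38.0 ± 5.4 CPM. *Xcr1* lies on chromosome 9 from 123852315 to 123862029 and *Hc* on chromosome 2 from 34983331 to 35061438, both protein coding on the minus strand of GRCm38. None of these 24 genes passed edgeR's threshold over all genes (adjusted p 0.203 for each). All 24 passed that of DESeq2, with adjusted p of 1.43e-04 or less.

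**Figure D1:**
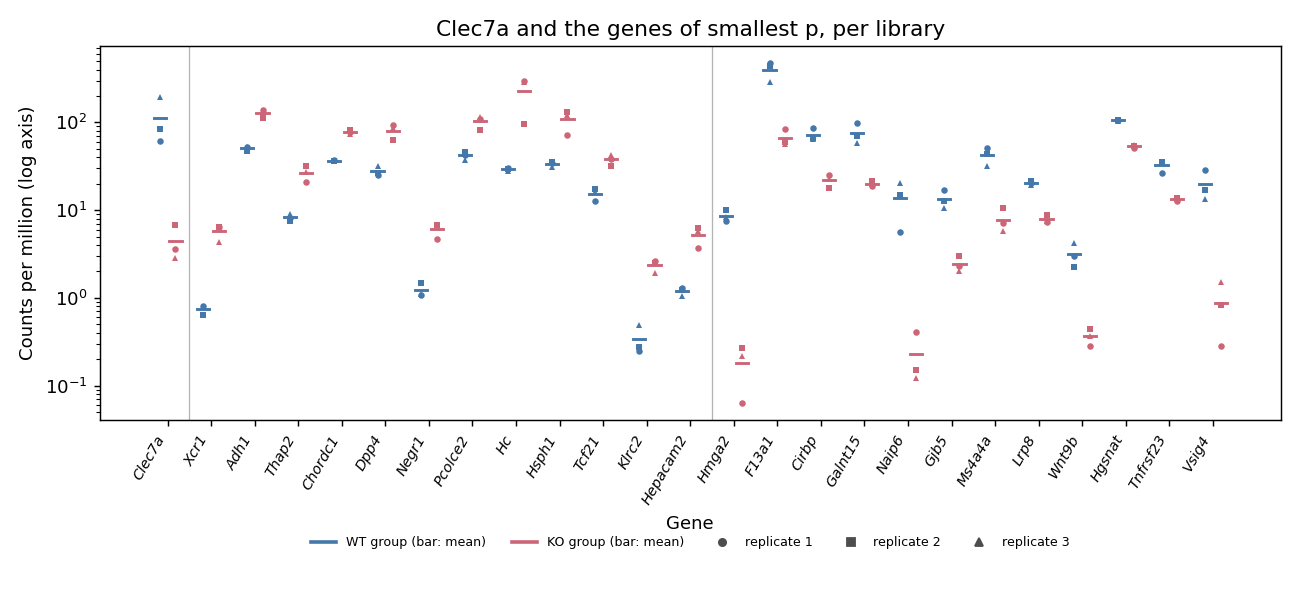
CPM on a log axis for *Clec7a* (left), the 12 genes of smallest p that were higher in KO (middle) and the 12 that were lower (right), with 1 point per library and a bar at each group mean (n = 3). The 24 genes beside *Clec7a* were ranked by p only among genes whose WT and KO libraries do not overlap, so their separation was fixed by the choice. Of all tested genes 21.1% had no overlap. Examples in WT against KO are *Hmga2* at 8.62 against 0.18 CPM and *Hc* at 29.1 against 228.0 CPM.

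Over all 16633 genes tested, edgeR's quasi-likelihood test called 0 genes higher and 0 lower at a Benjamini-Hochberg adjusted p under 0.05, with or without the 2-fold threshold, and its smallest adjusted p was 0.203. At an unadjusted p under 0.05 it had 1968 genes, 989 higher and 979 lower, which is 11.8% of those tested. limma-voom also called 0, whereas DESeq2 called 356 genes higher and 322 lower and limma-voom with sample weights called 1204 and 1017. The 3 KO values lay above all WT values for 1631 genes and below them for 1886, together 21.1% of the genes. Genes correlate with each other, and another grouping of the 6 libraries had 2505 genes at an unadjusted p under 0.05, more than the 1968 between the genotypes. The common biological coefficient of variation was 0.392. In simulated counts with this spread edgeR recovered 6% of 2-fold, 74% of 4-fold, 88% of 8-fold and 98% of 16-fold changes. The simulated genes varied independently of each other, unlike the real ones. These shares are therefore not the power of the real fit, in which *Clec7a*, 25.6-fold lower in KO, had an edgeR adjusted p of 0.203.

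Gene lists were tested beside single genes. Of 44 lists tested with camera at a preset correlation of 0.01, 11 were higher in KO and 5 were lower. With a correlation estimated for each list 0 passed, and with fry 2 passed, the natural killer (NK) cell list and the neighbours of *Clec7a*. At the preset correlation other groupings of the 6 libraries gave up to 25 lists. No member of any list passed edgeR over all genes (adjusted p of 0.203 or more). The counts below therefore give members past the threshold when adjusted over the list alone, beside those that DESeq2 called over all genes. Adjustment over the list alone was not part of the fixed design and does not correct for the 44 lists. Where many members have a small p it removes few. In the NK list 17 passed and 17 had an unadjusted p under 0.05, and in the T cell list 18 and 19. For each list the 2 members of highest mean CPM were named by the fixed rule, and the other examples were chosen after their values were seen.

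Most genes of NK, T and B cells had higher estimates in KO lungs, while the plasma cell list was not called. All 20 tested NK and cytotoxic genes had higher estimates, with a median log2 fold change of 1.67 (camera adjusted p 5.86e-16, and adjusted p = 0.237 with an estimated correlation). Of them 17 passed when adjusted over the list alone and DESeq2 called 9. *Il2rb*, an interleukin receptor chain, was at 8.67 ± 3.00 CPM in WT and 19.1 ± 8.05 in KO, and the chemokine gene *Ccl5* at 4.70 ± 1.33 and 10.8 ± 2.8 CPM (log2 fold changes 1.14 and 1.20). The inhibitory receptor gene *Klrc1* (2.39) and the granule gene *Nkg7* (1.97) had the smallest p, and 8 members of this list are receptor genes that lie beside *Clec7a*. Members of the *Klr* families share sequence, so counts of single members are uncertain. The 25 tested T cell genes were also all higher, with a median of 1.39 (camera adjusted p 2.71e-14, and adjusted p = 0.546 with an estimated correlation). Of these 18 passed over the list alone and DESeq2 called 12, among them the T cell receptor chains *Cd3g* (2.00, from 1.73 ± 0.42 to 6.95 ± 2.01 CPM) and *Cd3d* (2.05). The 2 most abundant T cell members, *Tcf7* (0.22 ± 0.43) and *Il7r* (0.72 ± 0.39), were within 2 SE of 0. B cell genes had a median of 1.07, with 17 of 18 higher, 6 past the threshold over the list alone and 6 called by DESeq2 (camera adjusted p 3.23e-08, and adjusted p = 0.707 with an estimated correlation). The abundant B cell members *Cd37* (-0.49 ± 0.32) and *Cd22* (0.70 ± 0.48) went opposite ways, while the transcription factor gene *Spib* (1.67) and the complement receptor gene *Cr2* (2.19) had the smallest p. WT replicate 1, which stood apart, was lowest on the B cell list (-1.30, against -0.45 and 0.06 in WT replicates 2 and 3) and also on the T cell (-1.08), dendritic cell (-0.93) and antigen presentation (-0.84) lists. Without it the B cell median was 0.79. The plasma cell list had 3 members higher and 9 lower of 12, with a median of -0.21 (camera adjusted p 0.585).

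Most dendritic cell, antigen presentation and interferon genes had higher estimates in KO as well. In the dendritic cell list 16 of 19 tested members were higher, with a median of 1.10, 6 past the threshold over the list alone and 5 called by DESeq2 (camera adjusted p 1.9e-08, and adjusted p = 0.546 with an estimated correlation). Examples were *Naaa* (0.65), the integrin gene *Itgax* (1.94 ± 0.67, from 46.4 ± 38.0 to 177.9 ± 66.4 CPM), *Xcr1* (2.94) and the lectin gene *Mgl2* (2.33). Of 19 antigen presentation genes 18 were higher, with a median of 1.04, 11 past the threshold over the list alone and 10 called by DESeq2 (camera adjusted p 1.09e-10, and adjusted p = 0.546 with an estimated correlation). The MHC class II genes led this list: the invariant chain gene *Cd74* was at 451.9 ± 132.2 CPM in WT and 1737 ± 602 CPM in KO (1.94 ± 0.37), and *H2-Aa* (2.03) and *H2-DMb1* (1.43) had the smallest p. The class I gene *H2-D1* had a log2 fold change of 0.62 ± 0.26. MHC genes are polymorphic and share sequence, so reads could be divided between them. Of 38 interferon response genes 36 were higher, with a median of 0.91, 5 past the threshold over the list alone and 6 called by DESeq2 (camera adjusted p 1.45e-13, and adjusted p = 0.546 with an estimated correlation). They included *Irf9* (1.05), *Ifi44* (1.70) and the GTPase gene *Iigp1* (0.61). KO replicate 1, which stood apart, had the highest mean of the interferon list at 0.99 above the mean of the 6 libraries, against 0.26 and 0.09 in KO replicates 2 and 3.

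The list of 36 tested genes that neighbour *Clec7a* on chromosome 6 had 30 members higher and 6 lower, with a median of 0.93 (camera adjusted p 3.57e-09, and adjusted p = 0.237 with an estimated correlation). Of these 11 passed over the list alone, all higher, and DESeq2 called 11. The NK receptor genes *Klrc2* (2.78) and *Klrc1* (2.39) had the smallest p in it, and 8 of its members are also on the NK list. The most abundant members, the membrane protein genes *Emp1* (-0.59 ± 0.49) and *Gprc5a* (-0.45 ± 0.59), were at 1022 ± 321 and 571.8 ± 413.3 CPM in WT and differed from KO by about their error.

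**Figure D2:**
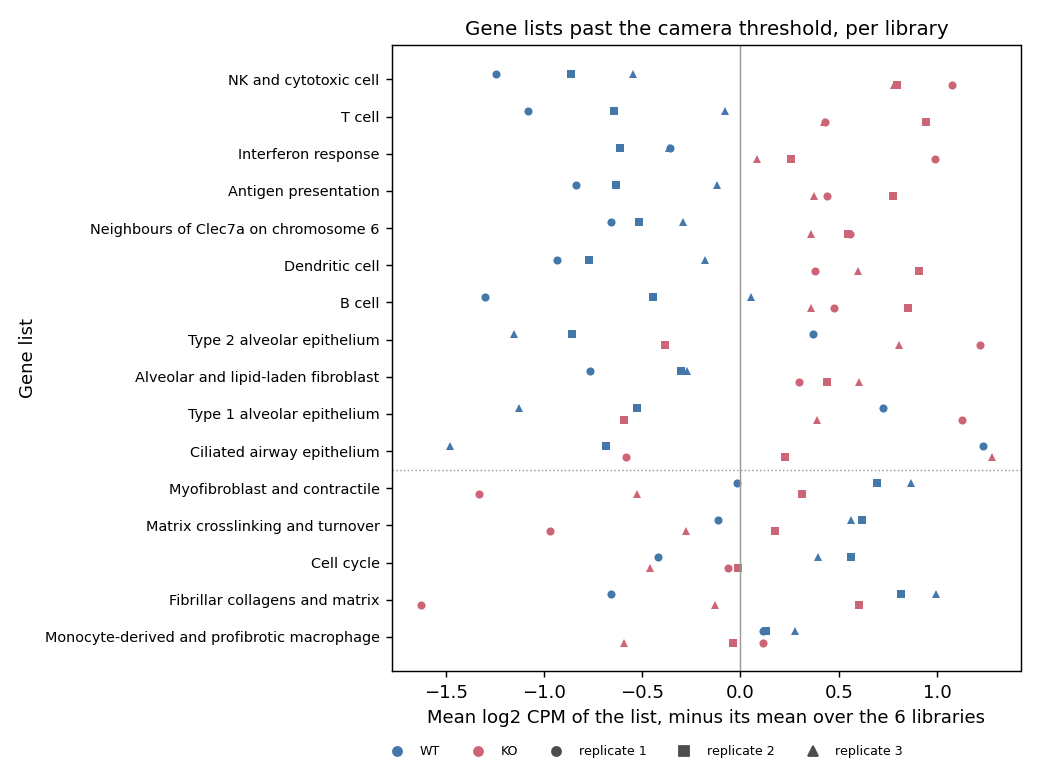
Mean log2 CPM of each of the 16 lists past the camera threshold, minus the list's mean over the 6 libraries, with 1 point per library, WT in blue and KO in red. The NK list separates the genotypes (WT at -1.24, -0.86 and -0.54, KO at 1.08, 0.80 and 0.78), whereas for fibrillar collagens (WT at -0.66, 0.82 and 0.99, KO at -1.63, 0.60 and -0.13) the libraries overlap.

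Markers of alveolar epithelium and of alveolar fibroblasts had higher estimates in KO. Of 25 type 2 alveolar genes 24 were higher, with a median of 0.71, 4 past the threshold over the list alone and 5 called by DESeq2 (camera adjusted p 1.75e-06, and adjusted p = 0.885 with an estimated correlation). The surfactant gene *Sftpc* was at 2548 ± 2390 CPM in WT and 6770 ± 6210 CPM in KO (1.41 ± 0.94), the desaturase gene *Scd1* had 1.34 ± 0.54, and *Hc* (2.97) and the alarmin gene *Il33* (1.99, from 36.5 ± 8.0 to 145.5 ± 80.8 CPM) had the smallest p. Leaving out WT replicate 1 moved the type 2 median to 1.52, and leaving out both first replicates, an alternative chosen afterwards, moved it to 1.28. The estimate for *Sftpc* ranged from 0.38 without KO replicate 1 to 2.53 without WT replicate 1. All 21 genes of the alveolar and lipid-laden fibroblast list were higher, with a median of 0.76, 4 past the threshold over the list alone and 5 called by DESeq2 (camera adjusted p 2.1e-06, and adjusted p = 0.265 with an estimated correlation). The growth factor gene *Bmp3* went from 13.3 ± 2.4 to 29.1 ± 0.9 CPM (1.13) and *Tcf21* was 2.46-fold higher in KO, while the abundant members *Macf1* (0.66 ± 0.55) and *Lpl* (0.08 ± 0.38) differed by about their error or less. Type 1 alveolar genes were higher in 17 of 20, with a median of 0.48, 0 past edgeR's threshold over the list alone, 2 at an unadjusted p under 0.05 and 1 called by DESeq2 (camera adjusted p 0.0141, and adjusted p = 0.885 with an estimated correlation). *Rtkn2* (2.39, and 1.56 without KO replicate 1) and *Vegfa* (0.80) had the smallest p there, and the abundant *Emp2* (-0.04 ± 0.65) and *Ager* (0.42 ± 0.77) did not differ beyond their error. The first replicates stood highest in their genotypes on both alveolar epithelial lists (type 1: 0.73 in WT and 1.13 in KO above the mean of the 6 libraries). Library means overlapped between the genotypes on both lists. KO replicate 2 lay at -0.39 (type 2) and -0.59 (type 1), below WT replicate 1 at 0.37 and 0.73. Ciliated cell genes were higher in 21 of 27, with a median of 0.35 and 0 members past edgeR at either level or called by DESeq2 (camera adjusted p 0.0384, and adjusted p = 0.885 with an estimated correlation). *Foxj1* (0.08 ± 1.00), *Tppp3* (0.16 ± 0.52), *Ccdc39* (1.39 ± 0.58) and *Dnah11* (1.05 ± 0.50) were examples, and without KO replicate 3 the estimates of *Ccdc39* and *Dnah11* were 0.82 and 0.53. The type 1 call ended without WT replicate 2, WT replicate 3 or KO replicate 1 (camera adjusted p 0.0541, 0.42 and 0.413), where its median was 0.31, 0.24 and -0.11, and the median was 1.10 without WT replicate 1 and 0.76 without KO replicate 2. The ciliated call ended without WT replicate 2, WT replicate 3 or KO replicate 3 (0.191, 0.946 and 0.677), where its median turned to -0.04, -0.13 and -0.25. WT replicate 1 was 1.24 above the mean of the 6 libraries on the ciliated list and KO replicate 1 was at -0.58, so the genotypes overlapped. The ciliated median was 1.66 without WT replicate 1 and 0.60 without KO replicate 1.

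The lists of contractile myofibroblasts and of the scar matrix had lower median estimates in KO at the preset correlation, with library means that overlapped between the genotypes. In the myofibroblast list 18 of 21 members were lower, with a median of -0.76, 7 past the threshold over the list alone and 5 called by DESeq2 (camera adjusted p 2.1e-06, and adjusted p = 0.885 with an estimated correlation). Smooth muscle actin *Acta2* was at 705.6 ± 173.8 CPM in WT and 269.2 ± 149.2 CPM in KO (-1.39 ± 0.45), and the tropomyosin genes *Tpm1* and *Tpm2* had -0.48 ± 0.21 and -1.31 ± 0.24. The profibrotic cytokine gene *Il11* was at 7.82 ± 4.07 and 1.19 ± 0.13 CPM (-2.72 ± 0.44), and 7 members of this list are also on the pericyte and smooth muscle list. Matrix crosslinking and turnover genes were lower in 27 of 34, with a median of -0.62, 0 past edgeR's threshold over the list alone, 10 lower and 2 higher at an unadjusted p under 0.05, and 6 lower and 1 higher called by DESeq2 (camera adjusted p 2.83e-05, and adjusted p = 0.885 with an estimated correlation). Lysyl oxidase-like *Loxl4* (-1.68) and the metalloproteinase gene *Mmp19* (-1.08) had the smallest p, and the abundant cathepsins *Ctsb* (-0.39 ± 0.30) and *Ctss* (0.01 ± 0.39) were within 2 SE of 0. Fibrillar collagen and matrix genes were lower in 26 of 34, with a median of -0.73 (camera adjusted p 0.0141, and adjusted p = 0.885 with an estimated correlation). Here edgeR passed 0 over the list alone and 2 at an unadjusted p under 0.05, *Fbln2* (-2.55) and the higher *Mfap4* (1.19), and DESeq2 called 1. Fibronectin *Fn1* was at 8793 ± 5947 CPM in WT and 4022 ± 3247 CPM in KO (-1.13 ± 0.95), and *Col3a1* had -0.66 ± 0.66. Without KO replicate 1 these estimates were -0.64 for *Fn1* and -0.27 for *Col3a1*, and without KO replicate 2 they were -1.88 and -1.21. The *Col3a1* estimate was also -1.04 without WT replicate 1 and -0.40 without WT replicate 3. The collagen call ended without WT replicate 2, WT replicate 3 or KO replicate 1 (camera adjusted p 0.0796, 0.215 and 0.594), where its median was -0.64, -0.42 and -0.48, and without KO replicate 2 the median was -1.23. KO replicate 1 had the lowest library mean on all 3 lists, and KO replicate 2 lay above WT replicate 1 on each of them (0.31 against -0.02 for myofibroblast, 0.18 against -0.11 for crosslinking and 0.60 against -0.66 for collagen genes). The myofibroblast median was -0.49 without KO replicate 1 and -1.18 without KO replicate 2, and the crosslinking median was -0.36 without KO replicate 1.

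Genes of monocyte-derived macrophages had lower estimates in part. Of 31 members 19 were lower and 12 higher, with a median of -0.44, 4 past the threshold over the list alone and 4 called by DESeq2, all lower (camera adjusted p 0.0274, and adjusted p = 0.885 with an estimated correlation). The arginase gene *Arg1* was at 647.5 ± 189.8 CPM in WT and 35.0 ± 27.6 CPM in KO (18.5-fold, -4.21 ± 0.64), osteopontin *Spp1* at 5927 ± 1295 and 2284 ± 1240 CPM (-1.38 ± 0.49), and the folate receptor gene *Folr2* had -1.40 ± 0.31. The lysosomal protease gene *Ctsd* had 0.36 ± 0.50. The call ended without WT replicate 3 or KO replicate 3 (camera adjusted p 0.102 and 0.361), where the median was -0.20 and -0.23, and without WT replicate 1 it was -0.29. On the FPKM table the macrophage list kept its call (adjusted p 0.0136) with a median of -0.13. Cell cycle genes were lower in 42 of 46, with a median of -0.40, 0 past edgeR's threshold over the list alone, 5 at an unadjusted p under 0.05 and 0 called by DESeq2 (camera adjusted p 1.74e-04, and adjusted p = 0.885 with an estimated correlation). *Ccnb2* (-0.85) and *Cenpa* (-0.57) had the smallest p, the proliferation markers *Pcna* (-0.02 ± 0.25) and *Mki67* (-0.28 ± 0.52) did not differ beyond their error, and the call ended without WT replicate 2 (camera adjusted p 0.0783, median -0.21). The cell cycle median was -0.67 without WT replicate 1. Library means overlapped between the genotypes on the macrophage and cell cycle lists. On the cell cycle list WT replicate 1 (-0.42) lay below KO replicates 1 and 2 (-0.06 and -0.01). On the macrophage list WT and KO replicate 1 were both at 0.115.

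Genes of the receptor's own family and pathway showed no common direction. Of 26 tested C-type lectin receptor and CARD9 signalling genes 13 were higher and 13 lower, with a median of 0.13 (camera adjusted p 0.655). The even split rests in part on 6 members that are also on the list of neighbours of *Clec7a*. All 6 had higher estimates, from 0.32 for *Clec2d* to 2.01 for *Clec1b*. Over the list alone 3 passed: *Clec7a* (-4.68) and the integrin gene *Itgam* (-1.70) were lower and the dendritic cell lectin gene *Cd209a* (2.96) was higher. The adaptor gene *Card9* (-0.16) and the kinase gene *Syk* (0.30) had an unadjusted edgeR p of 0.551 and 0.412, and the related lectin receptors *Clec4n* (1.03), *Clec4d* (-1.05) and *Clec4e* (-0.18) went different ways.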

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

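DESeq2, limma-voom with sample weights and the filters, scalings, block and FPKM fits were planned, while leaving out both replicate 1 libraries, the surrogate variable and the newer quasi-likelihood fit were chosen after seeing the data. The count of 0 genes in each direction came from edgeR with 1968 genes at an unadjusted p under 0.05, and the low-count filters, scalings, non-robust prior, limma-voom, FPKM fits and newer quasi-likelihood fit also gave 0. Counts higher and lower in knockout were 356 and 322 with DESeq2 (316 and 264 by at least 2-fold), 1204 and 1017 with sample weights (788 and 424), 289 and 383 with 1 surrogate variable (175 and 174) and 18 and 28 without both replicate 1 libraries (17 and 27). DESeq2's 678 genes included 618 of the 2221 called with sample weights, 325 of the 672 with the surrogate variable and 33 of the 46 without the replicate 1 libraries. The surrogate variable was low in both replicate 1 libraries (-0.57 and -0.56) and between 0.15 and 0.39 in the others. Leaving out single libraries gave 0 to 1 genes higher and 0 to 2 lower, with or without the 2-fold threshold. Without KO replicate 1 the gene was *Hnrnpa3* (log2 fold change 3.56), and without KO replicate 2 they were *Hc* (3.33), *Gm20716* (-14.11) and an unannotated model (-5.96), named after their values were seen. All 25 genes plotted (*Clec7a* and the 24 of smallest p) kept their direction where they had a value, in each setting run, and 25 passed with DESeq2, with sample weights and with the surrogate variable. The 24 were picked from these same libraries for lack of overlap and smallest p. Their kept direction was therefore largely fixed by the choice and is no added evidence. On log2(FPKM + 1), which understates the change of low genes, their estimates were smaller by over 1.5 times for *Hmga2* (-1.60 against -5.53), *Naip6* (-1.42 against -5.89), *Xcr1* (0.96 against 2.94), *Klrc2* (0.80 against 2.78), *Negr1* (0.86 against 2.30) and *Hepacam2* (1.11 against 2.14), and without the FPKM filter also for *Wnt9b* (-0.61 against -3.09). On log2(FPKM + 0.1) only *Naip6* moved by over 1.5 times. *Clec7a* passed with DESeq2 (-4.67, adjusted p 1.52e-14), sample weights (-4.57, adjusted p 0.0164) and the surrogate variable (-4.53, adjusted p 0.0316). Over all its alternatives it lay between -5.14 and -4.03, with adjusted p from 1.52e-14 to 0.747. The cause of these differences between tools was not tested. In the simulation, where genes varied independently of each other, DESeq2 recovered more 2-fold changes than edgeR and called more unchanged genes.

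Lists higher and lower in knockout numbered 11 and 5, 0 and 0 with estimated correlations and 2 and 0 with fry. Leaving out single libraries gave 9 to 16 higher and 4 to 8 lower. Of the 16 lists, 12 stayed past the threshold without WT replicate 2 or WT replicate 3, 14 without KO replicate 1 or KO replicate 3, and all 16 without WT replicate 1, KO replicate 2 or both replicate 1 libraries. Leaving out both replicate 1 libraries moved the medians of the ciliated list to 2.04, the type 2 alveolar list to 1.28 and the cell cycle list to -0.69. On FPKM all 16 passed, and medians were smaller by over 1.5 times for the monocyte-derived macrophage list (-0.13 against -0.44), the T cell list (0.88 against 1.39), the NK list (0.93 against 1.67), the cell cycle list (-0.26 against -0.40) and the neighbours of *Clec7a* (0.55 against 0.93). A pseudocount of 1 understates the change of low genes, but the macrophage list is not low, with a WT mean of 7.43 log2 CPM. The cause of these smaller medians was not tested. The signs of 11 genes whose estimates lay near 0 or within about their error turned, and the cause was not tested. Limma-voom gave -0.041 for *Ctss* and 0.18 for *Emp2*. Sample weights gave -0.26 for *Ctss*, -0.25 for *Ctsd*, 0.36 for *Emp2* and -0.20 for *Lpl*. Without both replicate 1 libraries *Ctss* was -0.36, *Ctsd* -0.42, *Emp2* 0.52, *Lpl* -0.18 and *Gprc5a* 0.17. Total counts gave 0.011 for *Emp2* and 0.027 for *Pcna*, and the surrogate variable 0.079 for *Emp2* and 0.00073 for *Mki67*. On FPKM, *Emp2* was 0.24 in all 3 fits and *Pcna* 0.0048, 0.0045 and 0.0048. Leaving out single libraries gave ranges of -0.20 to 0.29 for *Ctss*, -0.34 to 0.68 for *Ctsd*, -0.11 to 0.47 for *Tcf7*, -0.43 to 0.90 for *Emp2*, -0.12 to 1.52 for *Ager*, -0.16 to 0.88 for *Tppp3*, -0.65 to 1.84 for *Foxj1*, -0.18 to 0.31 for *Lpl*, -0.30 to 0.14 for *Pcna*, -0.69 to 0.076 for *Mki67* and -0.83 to 0.29 for *Gprc5a*. With single libraries left out, estimates that kept their sign but moved by over 1.5 times were those of *Ctsb* (-0.51 to -0.22), *Il7r* (0.48 to 1.11), *Cd37* (-0.74 to -0.28), *Cd22* (0.32 to 1.16), *Macf1* (0.31 to 1.00), *Emp1* (-0.85 to -0.23), *Fn1* (-1.88 to -0.64), *Col3a1* (-1.21 to -0.27), *Ccdc39* (0.82 to 2.06), *Dnah11* (0.53 to 1.45), *Rtkn2* (1.56 to 3.04) and *Sftpc* (0.38 to 2.53). Over all alternatives run, the smallest estimates in size were -1.38 for *Il11* (main fit -2.72), 0.90 for *Klrc1* (2.39), 0.80 for *Cr2* (2.19) and 1.21 for *Cd3d* (2.05).

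Whether the replicate numbers pair the samples is not stated by the labels, and the values here do not settle it. Deviations from the group means of same-numbered libraries correlated across genes at 0.35, 0.35 and -0.10. KO replicate 1 correlated best with WT replicate 1, and WT replicate 3 correlated best with KO replicate 2 (0.47). The deviations within a group sum to 0, which constrains these correlations. With the replicate block edgeR called 0 genes in each direction and had 3387 at an unadjusted p under 0.05, and 13 lists were higher and 6 lower. Of the 16 lists, 15 passed with the block, all but the ciliated one (adjusted p 0.105, with a median of 0.73). The macrophage list had a median of -0.20 with the block. *Clec7a* was -4.56 with the block (adjusted p 0.129), and *Ctss* and *Emp2* were -0.029 and 0.17.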

Other observations

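The tests of lymph node genes, of endothelium against T cells and without both first replicates were chosen only after the result was seen. The other tests were written before their own results. The pattern of *Cirbp*, *Hsph1* and *Chordc1*, which the heat-shock and clock tests address, was itself found by ranking genes in these libraries. Genes outside the fixed rule that are named here were chosen after their values were seen. Among the 28 lists that camera did not call, several held single genes that passed when adjusted over the list alone. In the list of inflammatory cytokines and chemokines (median 0.31, camera adjusted p 0.274) the monocyte chemokine gene *Ccl2* was lower (log2 fold change -1.67), and 25 of 37 members had higher estimates. Neutrophil genes had a median of -0.60 (camera adjusted p 0.145), with the chemokine receptor gene *Cxcr2* (-1.15) and *Stfa2l1* (-1.91) lower and *G0s2* (1.31) higher. The complement and coagulation list (median -0.13, camera adjusted p 0.158) held *F13a1* (-2.58) and the C5a receptor gene *C5ar1* (-1.14), both lower. Resident alveolar macrophage genes had a median of 0.61 with 14 of 20 higher, 0 past edgeR over the list alone, 4 at an unadjusted p under 0.05 and 4 called by DESeq2 (camera adjusted p 0.184), and KO replicate 1 lay 1.22 above the mean of the 6 libraries where the other 5 lay between -0.57 and -0.07. The hedgehog-interacting protein gene *Hhip* (2.42) passed over both the pericyte and smooth muscle list and the Wnt, Hedgehog and Notch target list. The endothelial list had a median of 0.14 (camera adjusted p 0.428), with the atypical chemokine receptor gene *Ackr1* (-1.85) lower.

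The list of type 2, type 17 and regulatory cytokine genes had members on both sides, 12 higher and 12 lower of 24 (median -0.03, camera adjusted p 0.614). *Arg1* (-4.21) passed over the list alone. Others with an unadjusted edgeR p under 0.05 were *Ccl24* (-2.48), *Il33* (1.99), *Gata3* (1.23), *Tbx21* (1.57), *Icos* (1.52), *Il17a* (2.94), *Il23r* (2.00) and *Il13ra1* (-0.53). TGF-beta response genes had a median of -0.05 (camera adjusted p 0.274) and nuclear-encoded respiratory chain genes one of -0.20 (camera adjusted p 0.178). The direction of the camera test was up while the median was below 0 for secretory airway genes (median -0.23, adjusted p 0.0838), heart and skeletal muscle genes (-0.15, 0.184), thymus, lymph node and adipose genes (-0.45, 0.298), Wnt, Hedgehog and Notch targets (-0.06, 0.691) and the type 2 and type 17 list. Adventitial fibroblast and mesothelium genes had a median of -0.04, a mean of 0.00067 and a test direction of down (adjusted p 0.585).

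The lists of lymphocytes, dendritic cells, interferon and antigen presentation were higher in KO together at the preset correlation, at which other splits of the libraries gave up to 25 lists, and all of these calls were lost with an estimated correlation (adjusted p 0.237 to 0.707). A lower share of fibroblasts would raise the markers of all other cell types alike. The T cell list was higher in KO by 1.07 log2 units more than the endothelium list, with a pooled SD of 0.351. List means rose by 1.20 for T cells and 0.13 for endothelium. KO minus WT was 1.09, 0.71, 0.62 and 0.62 for type 2, secretory, ciliated and type 1 cells and -0.24 for injury-associated epithelium. The SDs in WT were 0.81, 2.18, 1.40, 0.95 and 0.69 in that order. Only the type 2 difference exceeded its WT SD, and the secretory median log2 fold change was -0.23. The test thus rests on endothelium. Fibroblast lists did not fall together. KO minus WT list means were 0.89 for alveolar and lipid-laden fibroblasts (SD 0.27 in WT and 0.15 in KO, all 21 members higher). They were -0.15 for adventitial fibroblasts and mesothelium and -1.03 for myofibroblasts. The alveolar list argues against a lower share of all fibroblasts alike, but a lower share of myofibroblasts is not excluded. Receptor genes beside *Clec7a* do not carry the NK list alone: its 12 members elsewhere had a median log2 fold change of 1.57, all 12 higher. Their camera p, not adjusted over lists, was 2.89e-10, and 0.0172 with an estimated correlation. For the full NK list the unadjusted camera p was 1.33e-17, and 0.0108 with an estimated correlation, which did not pass once adjusted (0.237). For lymph node or thymus tissue in the KO samples, the 5 tested genes of such tissue had a median of 1.61, but *Cr2* (2.19) and *Fcer2a* (1.61) are B cell list members themselves and the other 3, *Ccl19* (2.12), *Dntt* (0.43) and *Ccl21a* (0.14), are too few, so these values decide nothing. The fixed list of thymus, lymph node and adipose genes had a median of -0.45 over 17 tested genes that went both ways, so such tissue stays open, and so do more lymphocytes in KO lung tissue itself, the biological explanation.

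Genes near *Clec7a* were frequent among the smallest p-values: 29 of the 104 tested within 5 Mb had an unadjusted p under 0.05, 27.9% against 11.3% elsewhere (Fisher's exact test p 3.28e-06). Of these 29, 20 were among the 30 C-type lectin and NK receptor genes, 19 of them higher in KO. Without those 30 the share was 12.2% (9 of 74, Fisher's exact test p 0.716), which is what a larger number of NK and T cells would give, as a hypothesis. Sequence of another strain carried with the targeted allele could also alter the receptor genes themselves, and it cannot be told apart from a change in cell numbers for those genes, because the counts hold no variants.

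Cold-inducible *Cirbp* was lower (-1.73) and the chaperone genes *Hsph1* (1.68) and *Chordc1* (1.08) were higher in KO. These genes were named only among genes without overlap between groups, so their lack of overlap is no added evidence. A difference in temperature or heat-shock response at collection is a candidate explanation. Of 17 other heat-shock factor targets 16 were higher, and the cold-inducible *Rbm3* was lower in all 3 KO libraries (-1.44). The median of the 17 was 0.25, between bounds set before the test was run but after these 3 genes had been picked from the same libraries. The fixed list of immediate early and heat shock genes was not called (median 0.25, camera adjusted p 0.46). Its library means were lowest in the first replicates of both genotypes (-1.08 in WT and -1.41 in KO) and 0.36 to 0.85 in the others. A different hour of collection would part clock genes of opposite phase, and their mean log2 fold changes differed by -0.33 with a pooled SD of 0.63. That lies under the lower bound of 0.5 by less than its spread, so neither explanation can be excluded, and an effect of genotype on these genes was not tested.

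The 6 libraries can be split into groups of 3 in 10 ways, so the share of splits cannot go under 0.1 with 10 splits. edgeR called 0 genes in the real split and 0 in the highest other, so 10 of 10 splits gave as many. At an unadjusted p under 0.05 it had 1968 genes in the real split, 2505 in the split that set WT replicate 1, KO replicate 1 and KO replicate 3 against the rest, and 1642 in the one that set both first replicates and WT replicate 2 against the rest. DESeq2 called 678 genes in the real split, and 2 of the 10 splits reached that number, the other being that of WT replicate 1, KO replicate 1 and KO replicate 3, with 872. The other 3 splits that set both first replicates on one side gave 11, 16 and 0, so the first replicates alone do not account for the 872. Without both first replicates edgeR called 18 genes higher and 28 lower. Camera called 16 lists in the real split and 24, 17, 23, 20, 20, 20, 24, 25 and 10 in the others. Of the 10 splits, 9 gave at least 16, the real one included. Every other split but the one with 10 lists thus gave more lists at the preset correlation than the genotypes did. Fry called 2 lists in the real split and 0 in each other split, so 1 of 10 gave as many.

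*Hmga2*, *Naip6*, *Vsig4* and *Arg1* were the named genes other than *Clec7a* with more than a 10-fold lower level in KO, at 46.1-, 59.1-, 22.3- and 18.5-fold. Their residual levels in KO were 0.18 ± 0.11, 0.23 ± 0.16, 0.88 ± 0.61 and 35.0 ± 27.6 CPM (SD, n = 3). The related genes *Naip2* (0.45 ± 0.33) and *Naip5* (0.40 ± 0.48) had small positive estimates.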
